A study of Homo sapiens with 100 samples.

How the data were processed

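The series holds 100 samples, of which 65 are chromatin immunoprecipitation libraries and 35 are input libraries. H3K27ac, H3K4me3 and H3K9ac were profiled in the buffy coat (the white cell layer of centrifuged blood) of patients with non-ulcer dyspepsia. The labels place each patient in a Delayed, Normal or Rapid gastric emptying group. One peak list per immunoprecipitation library was used. The input samples were not analysed here and enter only as the controls named in the file headers. Sample titles carry 25 donor codes, which differ within each group of a mark, and 18 codes have all 3 marks. The code of 1 library differs by a digit from that of its input library. It was used as written, so that 2 of the 25 codes may belong to 1 patient, and overlaps between marks leave that pair out. P-values therefore measure the spread between samples with different donor codes. Libraries are named here by group and a replicate number that has no order and joins no libraries across marks. Flow cells, read from the names of the files, are called A to F.

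The submitters' processing notes list CASAVA 1.4, BWA 0.5.9, SICER and MACS2 with the genome build hg19, without giving each its role. Per the file headers, peaks were called for each library against an input library, of the same donor code in 64 of 65 libraries, with MACS 2.0.10.20120913, with a q-value cutoff of 0.01, a tag size of 51 bp and narrow peaks. The headers also state that the larger data set was scaled towards the smaller. Positions on chromosome 1 reach 249240541, which lies beyond the end of that chromosome in GRCh38 and within its length in hg19. Per the file headers, each peak has a length in bp (end minus start plus 1) and a signal, the fragment pileup at the summit. The deposited lists also give the authors' fold enrichment, a ratio of that pileup to the local background, and the authors' p and q-values on the -log10 scale. These scores of a peak were used only within its own list, to rank or filter peaks, and were never compared between libraries. Positions are given on hg19, 1-based, with both ends included.

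Depth was taken from the file headers as the number of tags in the immunoprecipitation library. It ranged from 15.1 to 39.3 M for H3K4me3, from 1.42 to 70.3 M for H3K9ac and from 10.4 to 43.1 M for H3K27ac. Their input libraries had 8.76 to 29.1 M, 5.79 to 29.3 M and 16.3 to 32.0 M tags. The lists hold no read counts for regions without a peak, so the absence of a peak means that none was called at the depth of that library. Only the 22 autosomes were analysed. Sex chromosomes, mitochondrial DNA and unplaced contigs were left out so that nothing printed belongs to one person.

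Choices named in this paragraph were made before the data were examined. Autosomal peaks of all libraries of a mark were merged, and merged regions with a peak in at least 2 libraries were kept as consensus regions. A region was present in a library if a peak overlapped it by at least 1 bp. Presence was compared between Delayed and Normal and between Rapid and Normal with a two-sided Fisher exact test for each region with a peak in at least 3 of the libraries compared and missing in at least 3. The covered share of a region, the fraction of its length under peaks of a library, was compared with limma (eBayes with a trend) over the libraries of all 3 groups, with group and flow cell as terms, for regions with a peak in at least 3 libraries and missing in at least 3. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The autosomal length covered by peaks and the number of peaks per library were compared with two-sided exact permutation tests, with 95% intervals from inverting the test. Similarity of peak sets was the Jaccard index of covered bp. A one-sided exact permutation test asked whether pairs within a group were more alike than pairs between groups. A one-sided test with 100000 permutations asked the same of pairs within and between flow cells. Overlap between marks was the share of one mark's peaks that overlapped peaks of another mark in the libraries of the same donor code, given as a median without a test.

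The regions named in the text follow a fixed rule. For each mark and comparison these are up to 5 regions in each direction with the smallest Fisher p, whether or not they passed the threshold. Ties were broken by the difference in presence averaged over flow cells that hold both groups, then by the mean covered length, then by position. From the covered share test the rule takes up to 5 regions in each direction among those past the threshold. The core regions named for each mark fall outside this rule and were chosen after their values were seen.

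Alternatives chosen beforehand were a minimum of 10 for the authors' -log10 q-value, an equal number of peaks per library, a requirement that 50% of a region be covered, no filter on the number of libraries, tests stratified by or permuted within flow cells, no flow cell term, and leaving out each library in turn. The equal number was that of the shortest list of the mark, 9648 peaks for H3K4me3, 12014 for H3K9ac and 12392 for H3K27ac. Alternatives chosen after seeing the data were the covered length or the fragment length of a library as a further term in limma, limma weights for libraries, a fit on the flow cells that hold both groups alone, H3K9ac libraries of at least 10 M tags, and the overlap between marks and the flow cell comparison at the stricter and equal peak numbers. Leaving out a library changes which p-values the Fisher exact test can reach, so counts at an unadjusted p can move for that reason alone. Each test across regions was repeated on 100 splits of the same libraries. For the H3K27ac Rapid comparison the covered shares of each region were also shuffled within flow cells 100 times.

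Both region tests were tested on simulated data with the real numbers of libraries and 200 changed regions. With peaks in 95% of one group and 5% of the other, the Fisher exact test recovered 40.5% of changed regions in the H3K4me3 Rapid design and 43.5% in the H3K9ac Rapid design. It recovered 0 in the other 4 designs, although 86% to 99% of the changed regions there had an unadjusted p under 0.05. Each peak of an unchanged region was drawn at that region's mean rate, the same for every library. Differences between libraries in list length and flow cell were thus left out, and recovery in the real data may differ. For limma the covered shares of each region were shuffled within flow cells, which leaves out such differences between libraries of a flow cell too. With a shift of 0.6 in covered share, limma recovered 42%, 53.5% and 61.5% for Delayed in H3K4me3, H3K9ac and H3K27ac. For Rapid it recovered 0 in H3K4me3, 0 in H3K9ac and 20% in H3K27ac, where 55% to 87% of the changed regions had an unadjusted p under 0.05. On shuffled data without any change, limma called 0 regions in 5 designs and 1295 in the H3K27ac Rapid design. The weighted fit called 389 regions for H3K9ac Rapid, 384 for H3K9ac Delayed, 29 for H3K27ac Delayed and 11 for H3K27ac Rapid on such data, and its weights did not converge to the tolerance.

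Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Plots were drawn with matplotlib 3.10.9. The gene annotation at hand is on GRCh38, so no gene was assigned to a region, and tests of promoters, of gene lists and of cell type markers were not run.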

Results

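H3K4me3, H3K9ac and H3K27ac were profiled by ChIP-seq in buffy coat of patients with non-ulcer dyspepsia to compare delayed and rapid gastric emptying with normal gastric emptying. H3K4me3 marks active promoters, and the 2 acetyl marks are found at active promoters and enhancers. H3K4me3 lists came from 5 Delayed, 6 Normal and 9 Rapid libraries. H3K9ac lists came from 6 Delayed, 8 Normal and 9 Rapid libraries, and H3K27ac lists from 6 Delayed, 8 Normal and 8 Rapid libraries. The median depth in tags was 20.3 M for H3K4me3, 20.2 M for H3K9ac and 20.3 M for H3K27ac. In H3K9ac 4 libraries had fewer than 10 M tags. Normal H3K9ac libraries had 24.9 ± 20.2 M tags (SD, n = 8), Delayed 20.6 ± 9.11 M (SD, n = 6) and Rapid 17.9 ± 6.57 M (SD, n = 9).

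The number of peaks differed widely between libraries. Autosomal lists held 9648 to 31940 peaks for H3K4me3, 12014 to 58582 for H3K9ac and 12392 to 71290 for H3K27ac. Peaks covered 3.01 to 19.1 Mb of the autosomes in H3K4me3 libraries, 3.92 to 36.7 Mb in H3K9ac libraries and 4.15 to 73.3 Mb in H3K27ac libraries. The groups were spread unevenly over 6 flow cells. Rapid and Normal libraries shared flow cells B and D for H3K4me3 and H3K9ac and flow cell D alone for H3K27ac, where 2 Rapid libraries met 2 Normal ones. Values within flow cells are therefore given beside the pooled ones.

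**Figure D1:**
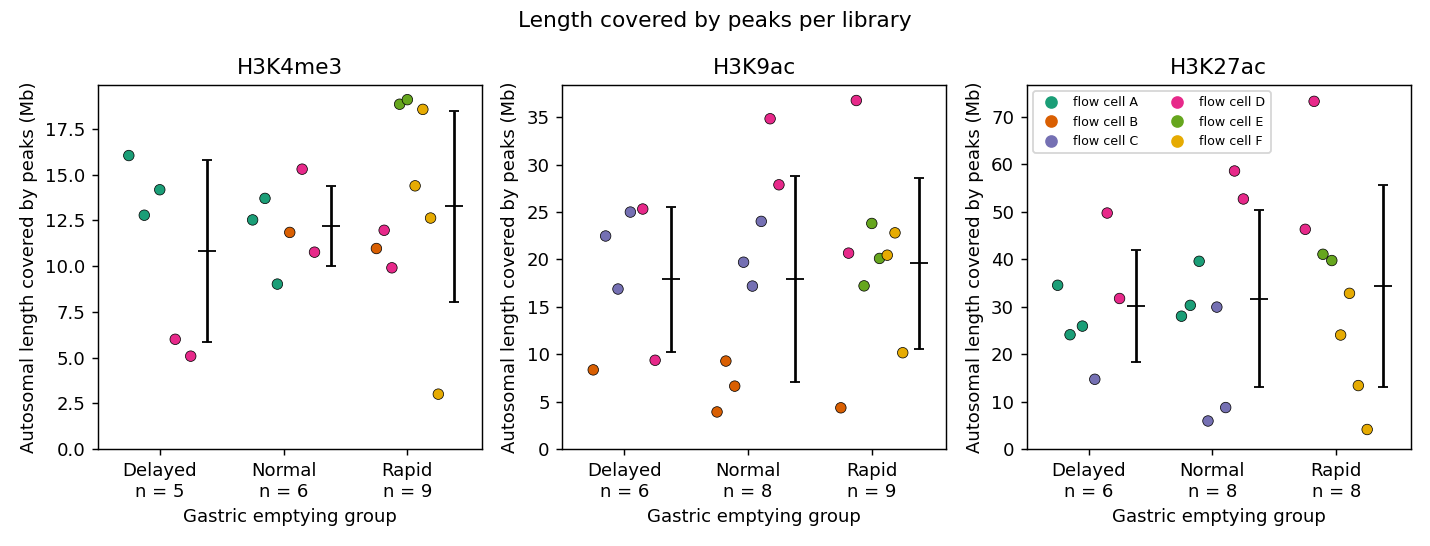
Autosomal length covered by peaks (Mb) for each library, by mark and gastric emptying group, coloured by flow cell; bars show the mean and SD. The range within each group exceeds the differences between group means, and H3K27ac libraries run from 4.15 to 73.3 Mb.

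Each mark had a core of regions present in every library. Merging gave 27022 H3K4me3, 53324 H3K9ac and 58376 H3K27ac regions with a peak in at least 2 libraries. Of these, 5663 H3K4me3, 5441 H3K9ac and 5131 H3K27ac regions had a peak in all libraries of the mark. Core regions were wide, with median widths of 1599, 1884 and 3164 bp for H3K4me3, H3K9ac and H3K27ac. Regions found in 2 libraries had median widths of 294, 317 and 348 bp. A region is the union of overlapping peaks, so its width can grow with the number of libraries, and this contrast is partly built in. The core regions with the most bp under peaks, by the median over libraries, were chosen after their values were seen. For H3K4me3 the first lay on chromosome 7 from 5458684 to 5468349, with a median of 7916 bp under peaks over 20 libraries. For H3K9ac it lay on chromosome 11 from 65184057 to 65193796, with a median of 9024 bp over 23 libraries. For H3K27ac it lay on chromosome 11 from 64617186 to 64648741, with a median of 24737 bp over 22 libraries. An H3K27ac region on chromosome 20 from 47365164 to 47401410 had a median of 24379 bp.

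**Figure D2:**
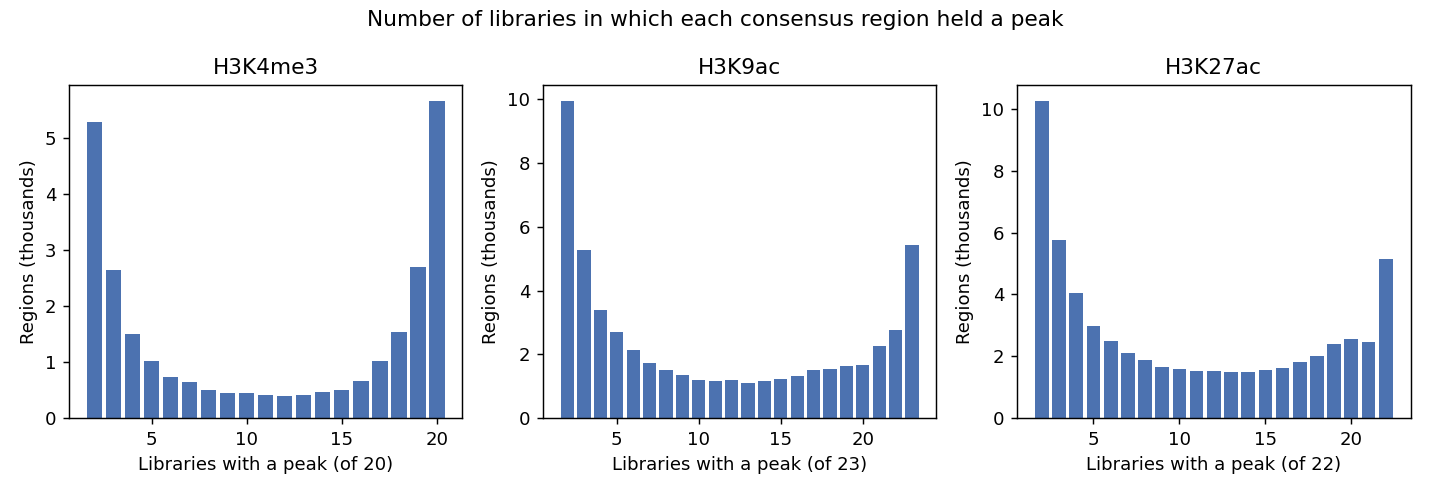
Number of consensus regions (axis in units of 1000) by the number of libraries in which they held a peak, for each mark. Counts are high at both ends, with 5663 H3K4me3, 5441 H3K9ac and 5131 H3K27ac regions present in all libraries.

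Most H3K4me3 peaks overlapped acetylated regions of the same donor code. A median of 77.1% of H3K4me3 peaks overlapped H3K9ac peaks of the same donor code (19 donors), and 66.3% overlapped H3K27ac peaks (18 donors). In the other direction 42.6% of H3K9ac peaks (19 donors) and 27.2% of H3K27ac peaks (18 donors) overlapped H3K4me3. A median of 79.5% of H3K9ac peaks overlapped H3K27ac, and 47.5% of H3K27ac peaks overlapped H3K9ac (21 donors each). Of the core H3K4me3 regions 100% overlapped an H3K9ac region and 99.2% an H3K27ac region, against 21.9% and 18.1% of the H3K4me3 regions found in 2 libraries. Core regions are wider, which favours an overlap of at least 1 bp, so this contrast is partly built in as well. A set of 2239 core H3K4me3 regions (39.5%) overlapped core regions of both acetyl marks. Some of these overlaps moved with equal numbers of peaks per library, which keeps the highest-ranked peaks of each list. The shares of H3K9ac and H3K27ac peaks with H3K4me3 then were 60.5% and 49.3%, and that of H3K27ac peaks with H3K9ac was 67.0%. The others moved less, to 76.3% of H3K4me3 peaks with H3K9ac, 66.2% with H3K27ac and 76.4% of H3K9ac peaks with H3K27ac.

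The first comparison asked whether H3K4me3 in Delayed patients differed from that in Normal patients. A region on chromosome 20 from 30134753 to 30135117 had a peak in 4 of 5 Delayed and 0 of 6 Normal libraries, as did a region on chromosome 10 from 81664065 to 81665120 (p = 0.0152 each, two-sided Fisher exact test). A region on chromosome 4 from 5893020 to 5893845 had a peak in 0 of 5 Delayed and 5 of 6 Normal libraries, as did a region on chromosome 7 from 2726797 to 2727510 (p = 0.0152 each, Fisher exact test). Stratified by flow cell, the exact p was 0.05 for the first 2 regions and 0.0167 for the other 2. On chromosome 5 from 176236876 to 176239287, 1 of 5 Delayed and 6 of 6 Normal libraries had a peak (p = 0.0152, Fisher exact test; stratified exact p = 0.0667). The 5 named regions more often present in Delayed all overlapped H3K9ac regions, and of the 5 less often present 1 did, against 61.4% of the 11834 regions tested by covered share.

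None of these H3K4me3 differences held after correction for the 5603 regions tested (lowest adjusted p = 0.976). The Fisher exact test called 0 regions, with 2 more often and 21 less often present in Delayed at an unadjusted p under 0.05, and 0 and 2 when stratified by flow cell. Leaving out 1 library at a time gave 2 to 113 and 29 to 159, the highest lower count without Delayed replicate 1. The balance turned to 105 and 29 without Delayed replicate 4 and 113 and 29 without Delayed replicate 5. By covered share limma also called 0 of 11834 regions, with 214 higher and 484 lower at an unadjusted p under 0.05 (64 to 330 and 258 to 864 over libraries left out). The balance turned to 231 higher and 47 lower at the stricter q-value and to 804 and 368 with covered length as a further term. It also turned without Normal replicate 5 (330 and 325), Delayed replicate 4 (275 and 265) or Delayed replicate 5 (301 and 258). H3K4me3 peaks covered 10.8 ± 4.96 Mb (SD, n = 5) in Delayed and 12.2 ± 2.20 Mb (SD, n = 6) in Normal libraries. That difference of -1.37 Mb (95% interval -6.69 to 3.57) was within the spread between libraries (p = 0.548, two-sided exact permutation test), as was the difference of -1.44 Mb within flow cells (p = 0.55, exact permutation). The latter averages unlike signs, with Delayed and Normal means of 14.3 and 11.7 Mb in flow cell A and 5.54 and 13.0 Mb in D. Delayed lists held 19642 ± 6218 peaks and Normal lists 22676 ± 2993 peaks (SD, p = 0.318, exact permutation test), a difference of -3034 and within flow cells of -3731 (p = 0.217, exact permutation). Libraries of one group were no more alike than libraries of different groups in the pooled test (Jaccard difference 0.0172, p = 0.156, one-sided exact permutation test). Within flow cells the difference was 0.0672 (p = 0.0333, one-sided exact permutation over 120 assignments), 1 of 6 such tests and not corrected for them. In flow cell D the Delayed lists covered 5.08 and 6.00 Mb and the Normal lists 10.8 and 15.3 Mb. Unequal covered lengths limit a Jaccard index, and this test was not repeated with equal numbers of peaks. It does not separate group from list length. With 5 against 6 libraries a fully separated region has p = 0.00216 and at least 243 of them would be needed to pass, so changes in fewer regions could not have been called by presence.

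The second comparison asked the same of H3K4me3 in Rapid patients. On chromosome 8 from 17434607 to 17435255, 7 of 9 Rapid and 0 of 6 Normal libraries had a peak, and the same counts were found on chromosome 19 from 36477960 to 36478404 (p = 0.00699 each, two-sided Fisher exact test; stratified exact p = 0.5). On chromosome 20 from 56801694 to 56802434, 0 of 9 Rapid and 5 of 6 Normal libraries had a peak (p = 0.002, Fisher exact test; stratified exact p = 0.167). The region on chromosome 4 from 5893020 to 5893845 had a peak in 0 of 9 Rapid libraries against the same Normal libraries as above (p = 0.002, Fisher exact test, and 0.333 when stratified). It appears in both comparisons, which share their Normal libraries. Of the 5 named regions more often present in Rapid 4 overlapped H3K9ac regions, and of the 5 less often present 0 did.

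After correction for 9000 regions the lowest adjusted p for H3K4me3 in Rapid was 0.92. The Fisher exact test called 0 regions, with 258 more often and 172 less often present in Rapid at an unadjusted p under 0.05, and 68 and 196 or 76 and 208 without Normal replicate 3 or 4 (54 to 262 and 17 to 208 over all libraries left out). Stratified by flow cell, 0 regions reached an unadjusted p under 0.05, since the lowest p observed was 0.167. Covered share gave 0 calls with limma, with 66 regions higher and 182 lower at an unadjusted p under 0.05 (49 to 116 and 32 to 294 over libraries left out), and 1 region lower when the covered length of each library was a further term. The balance turned to 659 higher and 279 lower without the flow cell term, 113 and 18 with fragment length, 57 and 31 at the stricter q-value and 150 and 50 with equal numbers of peaks. It also turned without Normal replicate 5 (116 and 64), Rapid replicate 8 (67 and 44) or Rapid replicate 9 (80 and 32). Rapid libraries had 13.3 ± 5.22 Mb (SD, n = 9) under H3K4me3 peaks. They differed from Normal by 1.07 Mb (95% interval -3.90 to 5.86, p = 0.652, two-sided exact permutation test) and within flow cells by -1.69 Mb (p = 0.5, exact permutation over 12 assignments, which allow no p under 0.167). Lists held 22289 ± 6927 peaks in Rapid (SD), a difference from Normal of -387 (p = 0.897, exact permutation test) and within flow cells of -4044 (p = 0.333, exact permutation). The Jaccard difference was -0.0097 (p = 0.508, one-sided exact permutation test) and within flow cells -0.12 (p = 0.667, exact permutation).

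For H3K9ac, Delayed and Normal patients were compared first. A region on chromosome 5 from 180634055 to 180634435 had a peak in 5 of 6 Delayed and 0 of 8 Normal libraries, as did a region on chromosome 6 from 158185453 to 158185914 (p = 0.003 each, two-sided Fisher exact test). Their p stratified by flow cell was 0.00625 and 0.0167 (exact test). Peaks on chromosome 6 from 88426878 to 88427589 were present in 0 of 6 Delayed and 7 of 8 Normal libraries (p = 0.00466, Fisher exact test; stratified exact p = 0.00833). On chromosome 9 from 75848574 to 75849631, peaks were present in 0 of 6 Delayed and 6 of 8 Normal libraries (p = 0.00966, Fisher exact test; stratified exact p = 0.00833). All 10 named regions overlapped H3K27ac regions, and 1 of them overlapped an H3K4me3 region, against 83.2% and 28.1% of the 32912 regions tested by covered share. Of the 254 regions higher by covered share at an unadjusted p under 0.05 (limma) 60.2% and 35.8% did, and of the 2072 lower 91.7% and 11.0%.

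The lowest adjusted p over the 23188 H3K9ac regions tested for Delayed was 1. The Fisher exact test called 0 regions, with 29 more often and 48 less often present in Delayed at an unadjusted p under 0.05. Stratified by flow cell they were 4 and 66, and without Normal replicate 1 or 3 they were 26 and 84 or 25 and 67. More regions were more often than less often present with equal numbers of peaks (50 and 42) and without any 1 of 12 libraries. These were Normal replicate 2 (26 and 24), 4 (62 and 5), 5 (55 and 6), 6 (50 and 11), 7 (37 and 25) or 8 (70 and 13) and Delayed replicate 1 (304 and 8), 2 (72 and 23), 3 (294 and 12), 4 (63 and 17), 5 (138 and 12) or 6 (52 and 18). These turns need not reflect the library left out, since the Fisher exact p-values that can be reached change with the number of libraries. With limma 0 of 32912 regions were called by covered share, with 254 higher and 2072 lower at an unadjusted p under 0.05 (143 to 841 and 794 to 3361 over libraries left out), and weighting the libraries gave 6 calls. The excess of lower regions was lost without the flow cell term (386 higher and 298 lower), with weighted libraries (738 and 311) and without Delayed replicate 3 (841 and 794). Peaks covered 17.9 ± 7.63 Mb (SD, n = 6) in Delayed and 17.9 ± 10.8 Mb (SD, n = 8) in Normal libraries (difference -0.0349 Mb, 95% interval -11.6 to 11.4, p = 0.992, two-sided exact permutation test). Within flow cells the difference was -3.38 Mb (p = 0.454, exact permutation), an average of unlike signs. Delayed and Normal means were 8.36 and 6.62 Mb in flow cell B, 21.4 and 20.3 Mb in C and 17.3 and 31.3 Mb in D. Delayed lists held 36497 ± 12218 and Normal lists 35414 ± 16165 peaks (SD), a difference of 1083 (p = 0.89, exact permutation test) and within flow cells of -3918 (p = 0.615, exact permutation). Libraries were no more alike within groups than between them (Jaccard difference -0.0251, p = 0.935, and -0.0195, p = 0.608, within flow cells, one-sided exact permutation tests). At least 155 fully separated regions (p = 0.000333 each, Fisher exact test) would be needed to pass by presence.

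H3K9ac in Rapid patients was then set against Normal. Peaks on chromosome 17 from 73641972 to 73642823 and on chromosome 12 from 4671236 to 4671750 were present in 7 of 9 Rapid and 0 of 8 Normal libraries (p = 0.00226 each, two-sided Fisher exact test; stratified exact p = 0.333). On chromosome 12 from 56101133 to 56102375, 9 of 9 Rapid and 3 of 8 Normal libraries had a peak (p = 0.00905, Fisher exact test, and 0.125 when stratified). Peaks on chromosome 2 from 135096019 to 135096398 and on chromosome 8 from 58846158 to 58846558 were found in 0 of 9 Rapid and 5 of 8 Normal libraries (p = 0.00905 each, Fisher exact test, and 0.167 when stratified). The 5 named regions more often present in Rapid overlapped no H3K27ac region, and 3 of them overlapped H3K4me3 regions. The larger set of 664 regions higher by covered share at an unadjusted p under 0.05 (limma) went the other way. Of these 84.3% overlapped H3K27ac and 8.89% H3K4me3, against 83.2% and 28.1% of those tested. All 5 regions less often present overlapped H3K27ac regions and none overlapped H3K4me3, and of 722 lower by covered share 90.6% and 11.1% did. Shuffled data without a change gave 7.43% of H3K9ac regions at such a p in this comparison, more than these sets together.

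Over 28152 H3K9ac regions the lowest adjusted p for Rapid was 1. The Fisher exact test called 0 regions, with 153 more often and 49 less often present in Rapid at an unadjusted p under 0.05, and 1 and 1 when stratified by flow cell. Without Normal replicate 1 they were 64 and 65, and over all libraries left out 39 to 203 and 2 to 65. Covered share gave 0 calls with limma, with 664 regions higher and 722 lower at an unadjusted p under 0.05 (168 to 1958 and 117 to 1294 over libraries left out). Higher regions were the more frequent in 5 of 9 alternatives (1229 and 719 with covered length as a further term) and without Normal replicate 4 (804 and 178), Normal replicate 5 (444 and 424), Rapid replicate 2 (1825 and 1294) or Rapid replicate 8 (1958 and 117). The number of calls became 55 without Rapid replicate 2, which had 1.42 M tags and was the only Rapid library in flow cell B. Rapid and Normal libraries then met in flow cell D alone. Without all libraries under 10 M tags the number was 0. It was 694 with weighted libraries, a fit that called 389 regions on shuffled data without any change. H3K9ac peaks covered 19.6 ± 9.02 Mb (SD, n = 9) in Rapid libraries, a difference from Normal of 1.66 Mb (95% interval -8.65 to 12.0, p = 0.734, two-sided exact permutation test). Within flow cells it was -2.48 Mb (p = 0.625, exact permutation over 24 assignments), and among libraries of at least 10 M tags -0.216 Mb. Rapid lists held 38286 ± 12247 peaks (SD), a difference from Normal of 2873 (p = 0.681, exact permutation test) and within flow cells of -6295 (p = 0.375, exact permutation). The Jaccard difference was -0.0061 (p = 0.546, one-sided exact permutation test) and within flow cells 0.0534 (p = 0.75, exact permutation).

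For H3K27ac, peaks in Delayed patients were compared with those in Normal patients. Peaks on chromosome 16 from 31380247 to 31380942, on chromosome 2 from 9308567 to 9309612 and on chromosome 3 from 151103601 to 151104899 were present in 0 of 6 Delayed and 6 of 8 Normal libraries (p = 0.00966 each, two-sided Fisher exact test). Stratified by flow cell, their p was 0.00833, 0.0333 and 0.00833 (exact test). On chromosome 22 from 47890640 to 47891503, 4 of 6 Delayed and 0 of 8 Normal libraries had a peak (p = 0.015, Fisher exact test, and 0.05 when stratified). On chromosome 19 from 43829313 to 43830353, 6 of 6 Delayed and 2 of 8 Normal libraries had a peak (p = 0.00966, Fisher exact test, and 0.0125 when stratified), although the difference turned to -12.5 percentage points when 50% of the region had to be covered. Lower covered shares were more numerous than higher ones, with 4483 of 37961 regions lower and 34 higher in Delayed at an unadjusted p under 0.05. These were 330 and 48 without the flow cell term, and 2569 of 35216 and 32 without Normal replicate 4, with 2569 to 5883 and 11 to 243 over all libraries left out.

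No H3K27ac region passed correction in Delayed. The Fisher exact test called 0 of 26011 regions (lowest adjusted p = 1), with 6 more often and 128 less often present at an unadjusted p under 0.05, and 1 and 187 when stratified by flow cell. Without Delayed replicate 2 they were 33 and 20, without Delayed replicate 5 36 and 36 and without Delayed replicate 6 59 and 16. Over all libraries left out they were 3 to 59 and 16 to 199. limma called 0 regions by covered share (lowest adjusted p = 0.142), and 81 lower without Delayed replicate 6. H3K27ac peaks covered 30.1 ± 11.8 Mb (SD, n = 6) in Delayed and 31.7 ± 18.7 Mb (SD, n = 8) in Normal libraries (difference -1.60 Mb, 95% interval -21.04 to 17.63, p = 0.847, two-sided exact permutation test). Within flow cells the difference was -6.68 Mb (p = 0.204, exact permutation). Delayed and Normal means were 28.2 and 32.6 Mb in flow cell A, 14.7 and 14.9 Mb in C and 40.8 and 55.7 Mb in D. The 2 Delayed libraries of flow cell D carry the same donor codes in every mark. Lists held 49819 ± 15146 peaks in Delayed and 48999 ± 20738 in Normal (SD), a difference of 820.4 (p = 0.93, exact permutation test) and within flow cells of -5648 (p = 0.41, exact permutation). The Jaccard difference was -0.0218 (p = 0.843, one-sided exact permutation test) and within flow cells -0.0363 (p = 0.667, exact permutation).

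H3K27ac in Rapid patients was the last comparison. By presence, a region on chromosome 16 from 84799989 to 84801374 and a region on chromosome 2 from 87062852 to 87063545 had peaks in 5 of 8 Rapid and 0 of 8 Normal libraries (p = 0.0256 each, two-sided Fisher exact test; stratified exact p = 0.333). Regions on chromosome 11 from 122394303 to 122395454 and on chromosome 9 from 110918519 to 110919141 had peaks in 0 of 8 Rapid and 5 of 8 Normal libraries (p = 0.0256 each, Fisher exact test, and 0.333 when stratified). By covered share 421 regions passed the threshold, 371 higher and 50 lower in Rapid. A region on chromosome 12 from 47631623 to 47632023 had the lowest p, with a mean covered share of 0.892 in the 2 Rapid and 0 in the 2 Normal libraries of flow cell D, and 0 in the Rapid and Normal libraries of other flow cells. Its fitted difference was 0.92 ± 0.141 (SE, adjusted p = 0.00516, limma). A region on chromosome 3 from 33875278 to 33875798 had means of 0.833 and 0 in flow cell D and 0 elsewhere (difference 0.855 ± 0.132, SE, adjusted p = 0.00516, limma). Among regions lower in Rapid, that on chromosome 2 from 87764185 to 87764600 had means of 0 in Rapid and 0.909 in Normal in flow cell D (difference -0.90 ± 0.165, SE, adjusted p = 0.00768, limma). Its means elsewhere were 0.0649 and 0.139.

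The 371 H3K27ac regions higher in Rapid had a peak in a median of 3 libraries, and 1.35% overlapped H3K4me3 and 15.1% H3K9ac regions, against 16.7% and 53.3% of the 37961 regions tested. The 50 lower ones were alike in this, with a median of 4.5 libraries, 0% and 20%. The regions tested had a peak in a median of 8 libraries, and rare regions overlap little in general. Of all H3K27ac regions found in 2 libraries 4.86% overlapped H3K4me3 and 14.6% H3K9ac regions. The 421 calls did not exceed what shuffled data gave. Rapid and Normal libraries met in flow cell D alone, and shuffling the covered shares of each region within flow cells gave 1069 to 1391 calls. It was 0 without the flow cell term, 0 with fragment length as a further term, 0 with weighted libraries and 0 in flow cell D alone. It was 48 without Rapid replicate 8, 8427 without Rapid replicate 7, and between 184 and 271 without Normal replicate 1, 2, 3, 5, 6, 7 or 8 or Rapid replicate 1, 2, 4 or 6. The Fisher exact test called 0 of 33710 regions (lowest adjusted p = 1), with 25 more often and 18 less often present at an unadjusted p under 0.05. Less often present regions were the more frequent with equal numbers of peaks (20 and 30) and without Normal replicate 1 (30 and 61), 2 (28 and 48), 6 (26 and 174), 7 (31 and 99) or 8 (25 and 160) or Rapid replicate 3 (37 and 48) or 8 (33 and 80). Other libraries moved the counts the opposite way, to 277 and 18 without Rapid replicate 6, 221 and 18 without Rapid replicate 4, 150 and 35 without Normal replicate 5 and 128 and 38 without Normal replicate 3. Here too the Fisher exact p-values that can be reached changed with the number of libraries. Stratified by flow cell none could pass, since the lowest p observed was 0.333. H3K27ac peaks covered 34.4 ± 21.4 Mb (SD, n = 8) in Rapid libraries, a difference from Normal of 2.62 Mb (95% interval -18.9 to 24.3, p = 0.796, two-sided exact permutation test) and within flow cell D of 4.14 Mb (p = 1, exact permutation over 6 assignments, which allow no p under 0.333). Lists held 48850 ± 18964 peaks in Rapid (SD), a difference from Normal of -149 (p = 0.988, exact permutation test) and within flow cell D of -5965 (p = 1, exact permutation). The Jaccard difference was -0.0203 (p = 0.898, one-sided exact permutation test) and within flow cell D -0.217 (p = 1, exact permutation).

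Peak sets were more alike within flow cells than between them for the acetyl marks. For H3K9ac the mean Jaccard index was 0.496 for the 46 pairs of one flow cell and 0.406 for the 207 pairs of different flow cells (p = 0.00031, adjusted p = 0.000465 over 3 marks, one-sided permutation test). For H3K27ac it was 0.526 for 43 pairs and 0.411 for 188 pairs (p = 0.00018, adjusted p = 0.000465, permutation test). For H3K4me3 the means of 0.557 for 38 pairs and 0.531 for 152 pairs did not differ beyond the spread (p = 0.161, permutation test). No pair of libraries of a mark had an index above 0.753. With equal numbers of peaks the means were 0.529 and 0.440 for H3K9ac and 0.560 and 0.442 for H3K27ac (p = 2e-05 each, permutation test). For H3K4me3 they were 0.554 and 0.526 (p = 0.0903, permutation test). All differences kept their sign at the stricter q-value. All 4 H3K9ac libraries under 10 M tags lay in flow cell B, whose H3K9ac lists covered 3.92 to 9.29 Mb. Unequal covered lengths limit a Jaccard index, so for H3K9ac flow cell is not separated from depth or list length.

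**Figure D3:**
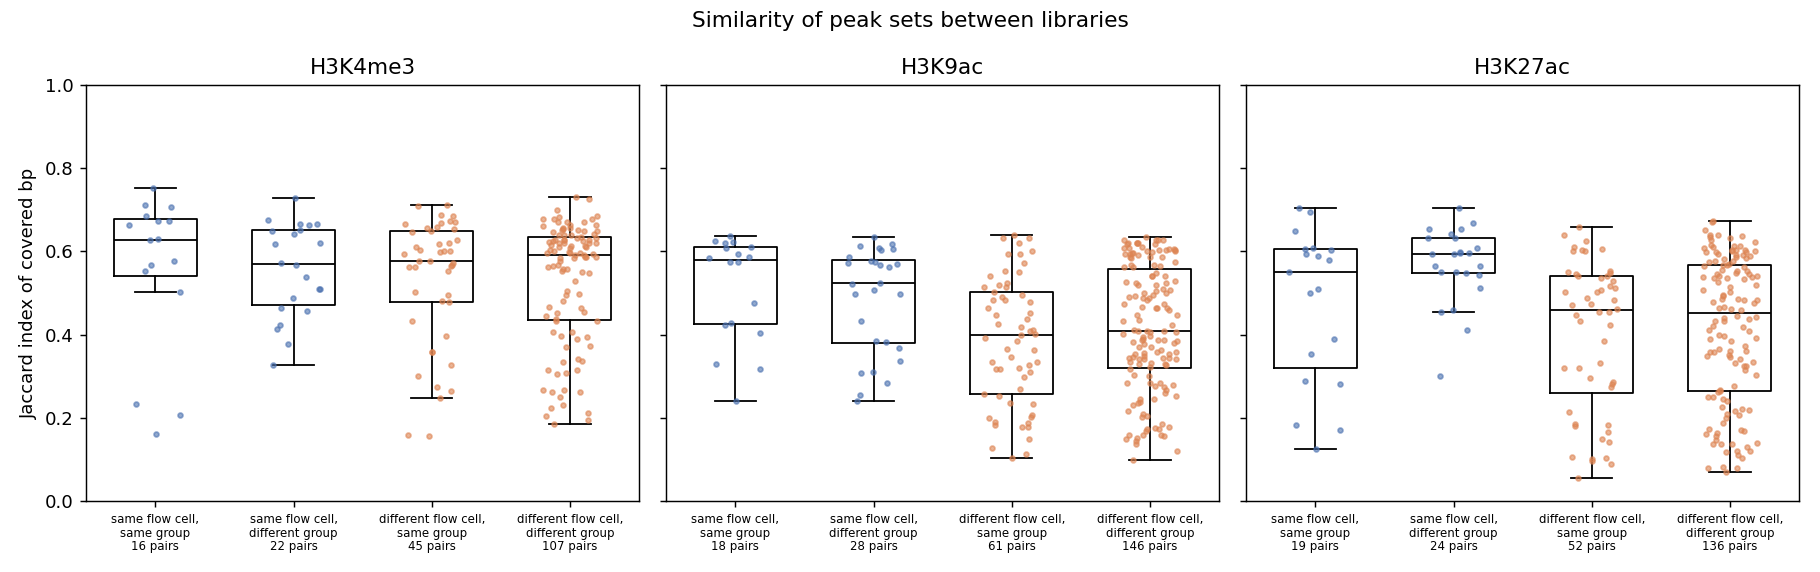
Jaccard index of covered bp for pairs of libraries of a mark, by whether the pair shared a flow cell and a gastric emptying group; boxes show the median and quartiles, whiskers reach the last value within 1.5 times the interquartile range, and points are pairs. For H3K9ac and H3K27ac pairs of one flow cell have higher means (0.496 and 0.526) than pairs of different flow cells (0.406 and 0.411).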

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

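No test in this part was chosen after the result was seen. Over 45 groups of libraries and measures, 3 held a library far from the others, where chance alone gives about 1 in 20. H3K9ac Normal replicate 3 had 70.3 M tags, with the nearest other Normal library at 25.4 M. Its input library had 9.05 M tags. H3K9ac Rapid replicate 2 had 1.42 M tags, with the nearest other Rapid library at 17.6 M. H3K4me3 Normal replicate 5 had a fragment length of 176 bp, with the nearest other Normal library at 164 bp. The causes were not tested.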

How the results depend on the processing

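The alternatives with a further term, weighted libraries, flow cells with both groups alone and H3K9ac libraries of at least 10 M tags, and those of the overlap between marks, were chosen after seeing the data. No paired analysis was possible because the labels tie no Delayed or Rapid patient to a Normal one. Tests of promoters, gene lists and cell type markers were not run, since the annotation is on another build than the files. Presence gave 0 calls in all 6 comparisons under every alternative run. This says little about stability, since on simulated data the Fisher exact test recovered 0 changed regions in 4 of the 6 designs. For H3K27ac at least 174 fully separated regions in Delayed and 105 in Rapid would be needed to pass. Stratified by flow cell, the lowest p observed was 0.167 for H3K4me3 Rapid and 0.333 for H3K27ac Rapid (exact test). In the H3K27ac Rapid comparison the 421 calls by covered share became 188 at an authors' -log10 q-value of at least 10, 190 with equal numbers of peaks, 686 without a filter, 261 with covered length as a further term, and 0 without the flow cell term, with fragment length as a further term, with weighted libraries or in the flow cell with both groups alone. In other comparisons the 0 calls by covered share became 1 (H3K4me3 Rapid, covered length as a further term), 6 (H3K9ac Delayed, weighted libraries) and 694 (H3K9ac Rapid, weighted libraries). Permuting within flow cells gave a covered length difference of -1.69 Mb for H3K4me3 Rapid and -2.48 Mb for H3K9ac Rapid, differences in peak number of -3918 for H3K9ac Delayed, -6295 for H3K9ac Rapid and -5648 for H3K27ac Delayed, and Jaccard differences of 0.0672 for H3K4me3 Delayed (past the threshold) and 0.0534 for H3K9ac Rapid (of the other sign). The stricter q-value turned the difference in peak number to 1145 for H3K4me3 Rapid and 2543 for H3K27ac Rapid, and equal numbers of peaks turned the covered length difference to 0.138 Mb for H3K9ac Delayed. Among libraries of at least 10 M tags the H3K9ac differences were -1401 peaks for Delayed and -0.216 Mb for Rapid. None of these differences in covered length or peak number was past the threshold in any setting, so their signs were not called. The share of H3K27ac peaks with H3K4me3 became 37.2% at the stricter q-value and 49.3% with equal numbers, that of H3K9ac peaks with H3K4me3 57.7% and 60.5%, and that of H3K27ac peaks with H3K9ac 67.0% with equal numbers. The causes were not tested.

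Leaving out each library in turn, the number of regions by covered share ran from 48 (without Rapid replicate 8) to 8427 (without Rapid replicate 7) for H3K27ac Rapid, from 0 to 55 for H3K9ac Rapid (without Rapid replicate 2) and from 0 to 81 for H3K27ac Delayed (without Delayed replicate 6). The covered length difference in Mb ran from -2.68 to 0.059 for H3K4me3 Delayed, positive without Delayed replicate 5. It ran from -2.04 to 2.38 for H3K9ac Delayed, positive without Normal replicate 4, 5, 6 or 8 or Delayed replicate 1, 3 or 5, and from -0.489 to 4.07 for H3K9ac Rapid, negative without Normal replicate 1 or Rapid replicate 9. For H3K27ac it ran from -5.53 to 2.24 in Delayed, positive without Normal replicate 4 or 5 or Delayed replicate 6, and from -2.94 to 6.94 in Rapid, negative without Normal replicate 6 or 8 or Rapid replicate 8. The difference in peak number ran from -1593 to 1194 for H3K4me3 Rapid, -2259 to 4393 for H3K9ac Delayed, -470.2 to 6182 for H3K9ac Rapid, -3925 to 4950.2 for H3K27ac Delayed and -4895 to 5059 for H3K27ac Rapid. The Jaccard difference ran from -0.0214 to 0.0134 for H3K4me3 Rapid and from -0.015 to 0.00511 for H3K9ac Rapid. The other H3K4me3 differences kept their sign but moved. In Delayed the Jaccard difference ran from 0.000414 to 0.0425 and the difference in peak number from -5056 to -1043. In Rapid the covered length difference ran from 0.341 to 2.35 Mb. Of the named regions, 8 differences in presence turned sign. At the stricter q-value these became, in percentage points, 3.33 on chromosome 3 from 57112414 (H3K4me3 Delayed), -25 on chromosome 1 from 231108083 (H3K9ac Delayed) and -8.33 on chromosome 10 from 63700762 (H3K27ac Delayed). With 50% of the region covered they became 20 on chromosome 16 from 89988928 (H3K4me3 Delayed), -12.5 on chromosome 1 from 231108083, -12.5 on chromosome 19 from 43829313 (H3K27ac Delayed) and -8.33 on chromosome 10 from 63700762, and with equal numbers of peaks -12.5 on chromosome 5 from 148620140 (H3K27ac Delayed). The causes were not tested. Presence of a peak is limited by depth, which was under 10 M tags in 4 H3K9ac immunoprecipitation libraries. Since the larger data set was scaled towards the smaller, the depth of the input can limit it too. H3K9ac Normal replicate 3, with 70.3 M tags and an input of 9.05 M, stayed among the libraries of at least 10 M tags.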

Other observations

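The splits of the covered share test, the shuffles within flow cells, the covered length test of the lower H3K27ac shares in Delayed, the settings with a further term and the test of donor codes with different input libraries were chosen only after the result was seen. H3K4me3 regions with an unadjusted p under 0.05 by covered share were compared with H3K9ac regions pooled over all groups. In Delayed 93.0% of the 214 higher regions and 14.5% of the 484 lower regions overlapped H3K9ac regions, against 61.4% of the 11834 tested. In Rapid these shares were 84.8% of 66 and 18.7% of 182. The higher and lower sets had a peak in a median of 5 and 4 libraries in Delayed and 9 and 3 in Rapid. For the regions tested the median was 6. Rare regions overlap little in general, and of H3K4me3 regions found in 2 libraries 21.9% overlapped H3K9ac. How much of the contrast follows from the number of libraries was not tested. Shuffled data without a change gave 3.71% of regions at such a p in Delayed and 1.90% in Rapid. Which direction was the more frequent changed with the setting in both comparisons. Both comparisons share their Normal libraries, and the difference between these sets was not tested. Of the 32912 H3K9ac regions tested 28.1% overlapped H3K4me3, against 35.8% and 11.0% of those higher and lower in Delayed at an unadjusted p under 0.05 and 8.89% and 11.1% in Rapid. For H3K27ac these shares were 83.2%, 60.2% and 91.7%, and 84.3% and 90.6%. Low H3K4me3 shares thus appeared in the lower set of Delayed and in both sets of Rapid. The higher and lower H3K9ac sets had a peak in a median of 5 and 8 libraries in Delayed and 4 and 4 in Rapid. For the H3K9ac regions tested the median was 8. Of H3K9ac regions found in 2 libraries 6.82% overlapped H3K4me3. These H3K9ac comparisons also share their Normal libraries. Shuffled data without a change gave 4.95% of H3K9ac regions at an unadjusted p under 0.05 in Delayed and 7.43% in Rapid, where the real data gave fewer (limma).

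Each test across regions was repeated on 100 splits of all libraries compared. Where the real count is 0 any split reaches it, so these splits say nothing about chance. For presence 100 of 100 splits reached the 0 calls in each of the 6 comparisons (highest other 0). For covered share 100 of 100 also did, with highest other counts of 162 and 17 for H3K4me3 Delayed and Rapid, 7 and 10 for H3K9ac and 66 for H3K27ac Delayed. The real grouping is counted as 1 of the 100. For the 421 calls of H3K27ac Rapid it alone reached the count (highest other 26). Such splits do not keep the flow cells of the groups. Of the 6 assignments within flow cell D, the real one included, 4 gave as many calls (highest other 6216). Chance is therefore not excluded for this count.

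The 421 H3K27ac calls in Rapid come from a fit in which Rapid and Normal libraries share flow cell D alone. A candidate explanation is a larger spread between the libraries of that flow cell than the fit allows, and 100 of 100 shuffles within flow cells gave as many calls (highest 1391). With covered length as a term the median difference in the called direction went from 0.674 (median SE 0.151) to 0.669 (SE 0.153), with 257 of 421 regions still called. Mean covered length in flow cell D was 59.8 Mb in Rapid and 55.7 Mb in Normal libraries. The term could therefore move the fit little, and it does not decide. With fragment length as a term the median difference was 0.633, with 0 still called because the SE rose to 0.208. Mean fragment length in flow cell D was 204.5 bp in Rapid and 177.5 bp in Normal libraries. Group and fragment length are therefore hard to separate there, and this fit does not decide whether fragment length accounts for the difference. Flow cells E and F hold only Rapid H3K27ac libraries, and each has its own term in the fit. The fitted difference therefore takes its Rapid values from flow cell D alone. Whether the Rapid and Normal libraries outside flow cell D differ in the same direction was tested separately. That test cannot decide, since 93.1% of their values are 0 (one-sided exact permutation p = 0.972, a reading chosen after the value was seen). Those Rapid and Normal libraries also share no flow cell.

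H3K27ac covered shares were lower in Delayed in 4483 regions at an unadjusted p under 0.05 (limma). Of 100 splits within flow cells, the real grouping included, 4 reached that count (highest other 5856). This was 1 of 12 tests of a comparison and a direction and was not corrected for them. With log covered length as a linear term 4161 of the 4483 regions (92.8%) stayed lower. Of all 37961 regions 4594 were lower with it at an unadjusted p under 0.05 (limma). The term did not remove the pattern, but a smaller covered length is not excluded. Mean covered length in Delayed and Normal was 28.2 and 32.6 Mb in flow cell A and 14.7 and 14.9 Mb in C. In D it was 40.8 and 55.7 Mb. Measured on the 4483 regions chosen for being lower, the median difference was -0.239 in flow cell A, 0 in C and -0.502 in D. Over all regions tested it was -0.0155, 0 and -0.22, largest in D as was the gap in covered length. The count was 330 (0.869% of the regions tested, against 11.8%) without the flow cell term and 2569 (7.29%) without Normal replicate 4, and 818 of the 7832 regions tested (10.4%) with equal numbers of peaks. A difference between Delayed and Normal patients may contribute, and so may differences between libraries within flow cells, and no test here separates these.

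The hypothesis that libraries of one donor code share variable regions across marks was tested on H3K9ac and H3K27ac. Over 14343 regions variable in both marks, the mean correlation of presence was 0.153 ± 0.061 (SD) for the same donor code and 0.0623 ± 0.0588 for other codes of the same flow cells, higher for the same code in 20 of 20 donors (p = 1e-05, one-sided permutation test, the smallest that 100000 permutations can give). An input library shared by both marks is argued against as the whole cause. Among the 9 codes with different input libraries for the 2 marks, the mean was 0.135 ± 0.0559 (SD) for the same code and 0.058 ± 0.0624 for other codes, higher in 9 of 9 (p = 0.00025, one-sided permutation test). Differences between patients may contribute, which was not tested.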
